A study of Arabidopsis thaliana with 6 samples.

How the data were processed

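Gene expression was measured in Arabidopsis thaliana embryos on 6 single-colour oligonucleotide arrays, 3 of wild-type and 3 of dcl1-15 embryos. Per the labels' protocols, each sample pooled 300 embryos dissected from the ovules, wild-type and mutant embryos were collected in turn in small lots, and biotin-labelled cDNA was amplified from 50 ng of RNA. The background is given as Ws, crossed repeatedly to Landsberg erecta, per the labels. The labels call the 3 samples of a genotype biological replicates and number them 1 to 3 in each genotype.

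The deposited table holds normalized log2 values for 17159 probe sets. The submitters' processing notes name GCRMA and MAS5, with no version and no statement of which made these values. How the rows of the table were chosen is not given in the sources used here. 19.4% of its probe sets had no value above log2 of 4 on any array. Scanner files and detection calls were not used here, so a value near the low end of about 2 has no stated distance from background, and each fold is a fold of normalized values. For arrays, the number of arrays limits the precision.

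The 37 array control probe sets were set aside, and 17122 probe sets were tested. The platform annotation used here named 1 gene for 9631 of these, several for 365 and none for 7126. The 9631 probe sets stand for 9531 different genes, of which 1293 have a symbol other than their locus tag. Of the 9631 probe sets, 9584 were found by gene identifier in the RefSeq gene table of assembly TAIR10.1. That table gave their symbols, their locus tags and the gene order along the chromosomes. Gene lists and symbol families were matched by these names. A gene with several probe sets was represented by the one with the highest mean over the 6 arrays.

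No probe set with a single named gene carried the name DCL1, so the level of the mutated gene was not analysed here and the genotype labels were not checked by it. The same holds for 14 other genes that were to be named whatever their value, LEC1, LEC2, FUS3, ABI3, WRI1, ASIL1, ASIL2, HDA6, SPL10, SPL11, PHB, CUC1, CUC2 and ARF17. Of the 415 genes on the lists fixed before the data were examined, 68 were measured.

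Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. A gene is said to have risen, fallen or changed only if it passed that threshold. Differences are dcl1-15 minus wild type on the log2 scale. Gene lists with at least 3 measured members were tested as sets with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, and the p-values were adjusted over the fixed lists and over the added lists separately. fry tests whether the genes of a set move, on balance, one way, and does not compare them with other genes. The known miRNA targets of the fixed lists were also tested together, with camera and with a two-sided permutation test of their median against 100000 random lists matched on mean expression.

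The 21 fixed lists covered miRNA targets (transcription factors, other proteins), trans-acting siRNA targets, the small RNA pathway, maturation regulators and their repressors, storage proteins, oil bodies, fatty acid synthesis, late embryogenesis abundant (LEA) proteins, photosynthesis, chlorophyll synthesis, the embryo's root and shoot poles, the cell cycle, auxin, flavonoids, heat shock and defence, endosperm, seed coat and reference genes. The trans-acting siRNA target, maturation repressor and endosperm lists had no measured member. A further 11 lists were added. The first 10 were written after it was known which gene names were measured and before any difference was seen. The last, further seed coat and endosperm markers, was written after the genes with the largest changes had been seen and before its members' own values were.

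The rule for the genes named was fixed in advance. It took the 5 largest changes in each direction among genes past the threshold whose groups did not overlap, up to 2 members past the threshold with the largest change from each fixed list, and 16 genes whatever their value. It was applied to the added lists too. Any other gene named was chosen after its values were seen.

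The 3 pairs of same-numbered arrays had correlations of 0.48, 0.21 and 0.36 between their deviations from the group means, all above 0.1, so the shared numbers were taken to pair the samples. Wild type 2 correlated more with dcl1-15 replicate 3, at 0.31, than with its own number, and wild type 3 with dcl1-15 replicate 2 at 0.15. These unmatched pairs are also above 0.1. Deviations from a group mean sum to 0, so a number 1 array that stands apart in both genotypes raises the correlations among the others. Pairing of the arrays numbered 2 and 3 is therefore not shown. This pairing comes from the data, since the labels do not say what a shared number marks. The fit without the pairing is the one reported, and a fit with the replicate number as a block is an alternative. The arrays numbered 1 stood apart in both genotypes. Their mean BioB spike-in control value was 8.61 in wild type and 8.57 in dcl1-15, against 7.40 to 7.87 on the other arrays.

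The other alternatives were eBayes without the trend or with robust fitting, 2 filters on dim probe sets, quantile normalization, centring on the median or on the reference genes, a floor at log2 of 4, leaving out each array, a 2-fold minimum, treat at 1.5-fold, Welch's test, 1 probe set per gene, camera on ranks and the mean of a gene's probe sets. Centring on the reference genes rests on 2 measured genes. It moved the median difference of all probe sets from -0.07 to -0.20.

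The fit was tested on simulated data for this comparison over 17122 probe sets. It recovered 37% of 100 simulated 2-fold changes and 75% of 100 simulated changes of log2 2, with 4 false calls. camera recovered all of 100 sets of 10 genes shifted by log2 1, with 1% false calls, and fry recovered all of them, with 2%. The simulated noise was independent between genes and between arrays. These rates therefore do not cover sets whose genes vary together or deviations shared by arrays. In both simulations the share of probe sets changed was far smaller than the 39.1% called in the data. The Benjamini-Hochberg adjustment depends on that share, so the share recovered in the real comparison may differ from these rates. In the data the estimated correlation was 0.31 for the storage list, 0.36 for cell division and 0.71 for LEA genes.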

Results

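Embryos homozygous for dcl1-15, a mutant allele of DCL1, were compared with wild-type embryos on 6 arrays, 3 per genotype. DCL1 encodes the Dicer-like enzyme that cuts most plant microRNAs (miRNAs) from their precursors, so the comparison asks which transcripts differ in embryos with a defect in making them. Mutant embryos were picked from siliques in which normal siblings had reached the torpedo stage, the stage at which the 2 cotyledons elongate, and wild-type embryos were taken at that stage from DCL1/DCL1 siblings. The level of DCL1 itself was not analysed here, because no probe set with a single named gene carried its name, so the genotype labels were not checked by it. Levels are normalized log2 values, given as mean ± SD over the 3 arrays of each genotype. The medians of the 6 arrays lay between 6.36 and 6.49.

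All 5 measured seed storage genes, of 13 listed, rose in dcl1-15 embryos, as did 5 of 6 markers of seed coat and endosperm, with a median of 1.66. Of the added lists, 14 of 23 genes for cell division fell, and among 24 genes of meristems and lateral organs 11 fell and 2 rose. As sets the storage, marker, cell division and meristem lists had camera adjusted p = 2.21e-06, 0.0115, 8.72e-05 and 0.00653 at the preset correlation. With an estimated correlation none of them passed (camera adjusted p = 0.219, 0.225, 0.321 and 0.225 in the same order). The storage cupin gene AT1G03890 rose 261-fold from a low value of 2.59, and 98.0-fold with a floor at log2 of 4. PAP85, a vicilin-type storage protein, rose 70.5-fold, 44.9-fold without wild-type replicate 1 and 142-fold without wild-type replicate 3. The organ genes YAB3 and JAG fell by 3.90 and 3.55 on the log2 scale, and JAG by 1.90 with the floor. In total, 6702 of 17122 probe sets (39.1%) changed, 3140 upward and 3562 downward, and 3889 of them by at least 2-fold. Of the called probe sets, 3694 name 1 gene, 128 several and 2880 none, and the first stand for 3677 different genes, 1707 higher and 1970 lower.

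Among probe sets with a single named gene, the largest rise in the normalized values was that of AT1G65500, from 1.60 ± 0.24, at the low end of the scale, to 10.01 ± 0.31, and AT2G15010, AT1G29670 and AT2G38905 rose by 6.60 to 6.89. With a floor at log2 of 4 the rise of AT1G65500 was 6.01, below those of AT1G03890 (6.61) and PAP85 (6.14). The largest fall in the normalized values was that of AT1G29270, from 9.12 ± 0.36 to 2.31 ± 0.22, followed by AT5G47600, AT4G29030, AT4G29270 and AT2G18890, which fell by 4.78 to 5.89. With the floor AT5G47600 led at -5.54, AT4G29030 followed at -5.39 and AT1G29270 at -5.12, and 13 of the 50 named genes past the threshold had folds smaller by over 1.5 times. Without wild-type replicate 3 AT2G15010 rose by 7.48, and without wild-type replicate 1 AT4G29030 was 32.0-fold lower, against 48.3-fold with all arrays. The 3 values per genotype did not overlap in 52.5% of probe sets, where chance gives 10%. Higher calls made up 46.9% of all calls, and 36.1% when arrays were centred on the 2 reference genes measured, of which AT2G28390 differed by 0.39 ± 0.15 (SE) (adjusted p = 0.0729) and AT4G34270 by -0.12 ± 0.16 (adjusted p = 0.590). Limma called 0 of these 2, 1 had an unadjusted p under 0.05 and Welch's test called 1, as did limma with the floor. The arrays numbered 1 stood apart in both genotypes, and without them 8905 probe sets were called, 3990 higher and 4915 lower, against 2493 without those numbered 2 and 3151 without those numbered 3. Without dcl1-15 replicate 2 the lower calls numbered 2293.

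All 5 measured genes of the seed storage list rose, and all 5 also passed when adjusted over the list alone, beside 5 of the 6 seed coat and endosperm markers. The list holds 13 genes, and none of its cruciferin (CRU) or albumin (SESA) genes was measured. AT1G03890 went from 2.59 ± 0.54 to 10.61 ± 0.08 (limma adjusted p = 2.74e-06) and PAP85 from 5.94 ± 1.78 to 12.08 ± 0.06 (adjusted p = 3.39e-04). The cupins AT2G18540, AT2G28490 and AT4G36700 rose by 5.38, 5.04 and 1.81. As a set the list had a mean difference of 5.28 and a median of 5.38 (camera adjusted p = 2.21e-06 over 9 fixed lists, and adjusted p = 0.219 with an estimated correlation). Both measured oil body genes rose, the oleosin AT3G01570 by 2.59 ± 0.18 (SE) and OLEO3 by 0.66 ± 0.11, and both passed over the list alone. Leaving out the arrays numbered 1 gave the same counts, 5 of 5 and 2 of 2.

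Genes for LEA proteins, which accumulate as seeds dry, did not move as a group. AT4G21020 rose from 4.24 ± 1.51 to 10.71 ± 0.27 and AtLEA4-1 from 6.85 ± 0.56 to 10.49 ± 0.21, in the whole comparison and over the list alone. Without wild-type replicate 3 the rise of AT4G21020 was 7.34, against 6.47 with all arrays. The other 8 of the 10 measured did not pass, and all 8 had wild-type means under log2 of 5. The list's mean difference was 0.53 and its median -0.32, of opposite sign (camera adjusted p = 0.810, and adjusted p = 0.943 with an estimated correlation). Leaving out the arrays numbered 1, 2 rose and 2 fell, and with the replicate number as a block 2 rose and AT3G53040 fell. 1 fell with quantile normalization, centring on the reference genes or without wild-type replicate 2, and 2 without wild-type replicate 1. The wild-type array numbered 3 held the highest wild-type value of 9 of the 10 genes. There M17 measured 8.01, against 2.27 and 2.00 on the other wild-type arrays and 1.86 to 1.99 in dcl1-15. PAP85 measured 7.97 on that array, against 4.64 and 5.22 on the other two. Without wild-type replicate 3 the mean of the LEA list was 1.17 (adjusted p = 0.172).

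**Figure D1:**
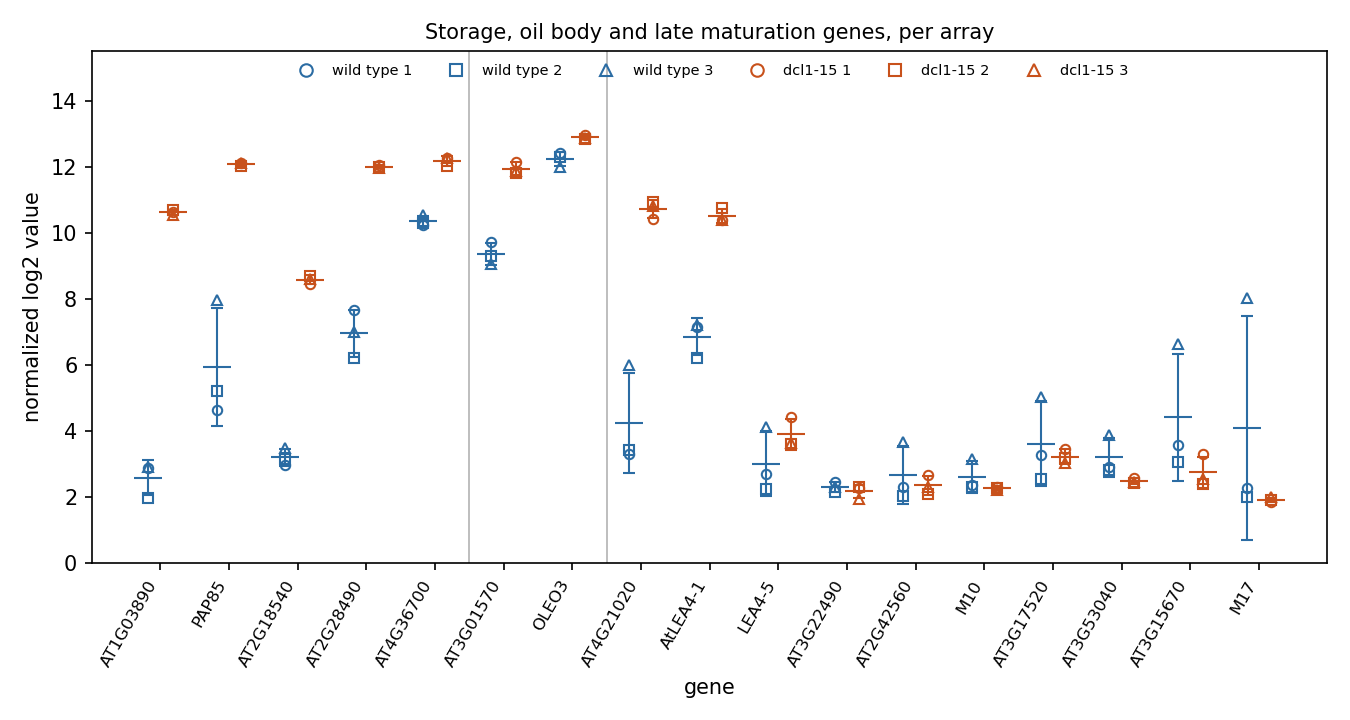
Normalized log2 values (vertical axis) of the 5 storage, 2 oil body and 10 LEA genes measured, with each array as a point and the mean ± SD of 3 arrays per genotype as bars. The dcl1-15 arrays lie above all wild-type arrays for every storage and oil body gene, and wild type 3 reaches 8.01 for M17.

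Of the 18 listed regulators of seed maturation, 3 were measured and 2 rose, also over the list alone. The MADS-box gene AGL18 rose by 1.77 ± 0.29 (SE) and EEL, a bZIP factor of late embryos, by 0.88 ± 0.11, while BZIP53 differed by -0.08 ± 0.14 (adjusted p = 0.672). The list did not pass as a set (camera adjusted p = 0.135). FaTA and FATB, the 2 measured genes of plastid fatty acid synthesis, did not pass in limma, and 0 passed at an unadjusted p under 0.05 or with Welch's test.

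Most measured markers of the seed tissues around the embryo rose. BAN, an enzyme of seed coat tannin synthesis and the 1 measured gene of the fixed seed coat list, rose from 2.58 ± 1.06 to 4.42 ± 0.50 (adjusted p = 0.0173, and past over the list alone). Of the 6 further markers, BAN included, 5 rose with a median of 1.66 (camera adjusted p = 0.0115, and adjusted p = 0.225 with an estimated correlation). DELTA-VPE, a protease gene of the inner seed coat, rose by 2.15 ± 0.52 (SE), the largest rise among them and 4.42-fold, against 2.82-fold without wild-type replicate 1 and 6.81-fold without wild-type replicate 2. The fifth to rise beside BAN, DELTA-VPE, SWEET11 and AT1G71250 was DFR, the 1 measured gene of the flavonoid list, which rose by 1.70 ± 0.50 (adjusted p = 0.0263, and past over the list alone). AT5G26630 differed by -0.15 (adjusted p = 0.491). BAN and DFR did not pass without dcl1-15 replicate 2 (adjusted p = 0.0613 and 0.0948) or replicate 3 (adjusted p = 0.0647 and 0.0957), and with a floor at log2 of 4 neither they nor DELTA-VPE passed. In 4 of the 5 storage genes the rise exceeded that of every marker. The size of a log2 rise depends on the wild-type level, and these 4 measured 1.97 to 7.97 on the wild-type arrays. DELTA-VPE, DFR, SWEET11 and AT1G71250 measured 6.60 to 10.48 there, and BAN and AT5G26630 1.53 to 3.65. The storage gene AT4G36700, at 10.24 to 10.53 there, rose by 1.81. When the arrays numbered 1 were left out, 5 of the 6 markers rose.

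**Figure D2:**
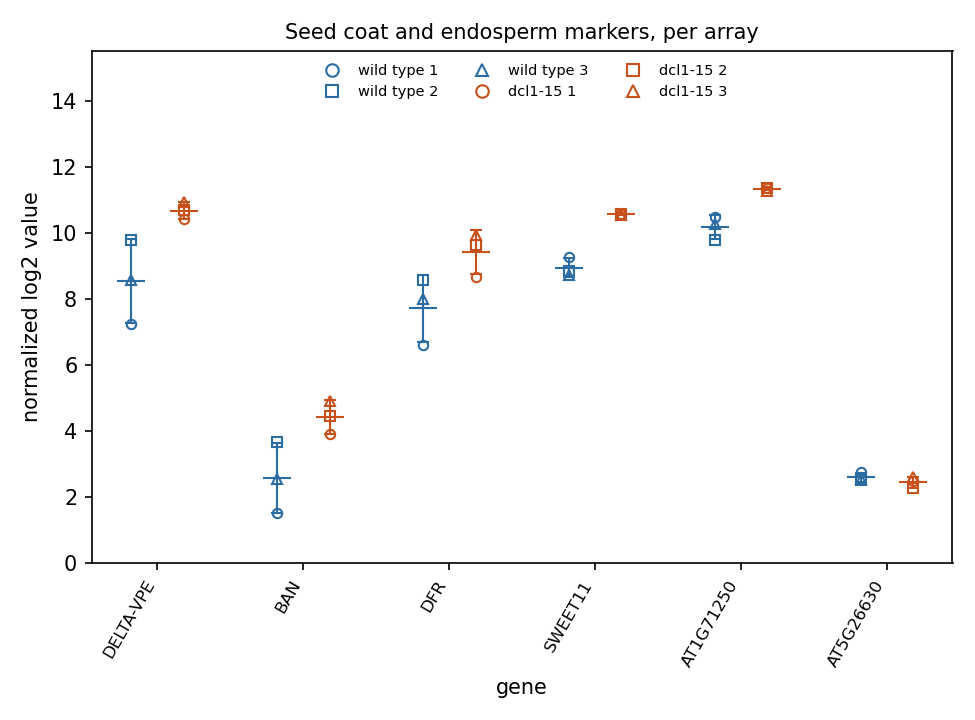
Normalized log2 values (vertical axis) of the 6 seed coat and endosperm markers measured, with each array as a point and the mean ± SD of 3 arrays per genotype as bars. The dcl1-15 arrays lie above all wild-type arrays for 5 genes, and AT5G26630 stays near the low end in both genotypes.

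Few known miRNA targets were measured, and those that changed rose. Of the 66 transcription factors and 44 other proteins listed as targets, 13 were measured, 4 rose and 9 did not pass. AGL16, a target of miR824, rose from 6.79 ± 0.74 to 8.82 ± 0.55 (adjusted p = 0.00474) and ARPN (plantacyanin), a target of miR408, from 6.41 ± 0.10 to 9.12 ± 0.24 (adjusted p = 3.71e-05). APS3, an ATP sulfurylase targeted by miR395, rose by 0.83 ± 0.23 (SE) (adjusted p = 0.0207), and the pentatricopeptide repeat gene AT1G63400 by 0.67 ± 0.17 from a low value of 2.34. All values of AT1G63400 lie below log2 of 4, and with a floor there it did not pass. With any 1 array other than wild-type replicate 1 left out, APS3 did not pass (highest adjusted p = 0.0769). PHV, a homeodomain gene targeted by miR166, differed by -0.36 ± 0.17 (adjusted p = 0.123), and fell when arrays were centred on the reference genes (adjusted p = 0.0433). Over each list alone, 1 of 2 transcription factors and 3 of 11 other proteins rose. They were 1 and 4 in the whole comparison when the arrays numbered 1 were left out, and with the replicate number as a block 4 of the 11 rose and 1 fell. Without dcl1-15 replicate 2, 1 of the 11 rose.

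The 13 targets together had a mean difference of 0.58 and a median of 0.27 (camera p = 0.0361, and p = 0.0908 with an estimated correlation). The permutation test of their median gave p = 0.150, against a median of -0.06 over random lists. The camera call was lost without wild-type replicate 3, at a mean difference of 0.55, and without dcl1-15 replicate 3, at 0.57. The 11 targets that are not transcription factors did not pass on their own (camera adjusted p = 0.114), nor did 6 further targets on an added list (adjusted p = 0.702), of which limma and Welch's test called 0 and 0 had an unadjusted p under 0.05. With the replicate number as a block, without wild-type replicate 1 or without both arrays of that number 1 of the 6 rose. In the small RNA pathway, SE and TGH, cofactors of miRNA processing, fell by 0.83 and 0.72, also over the list alone. Neither passed without dcl1-15 replicate 2 (adjusted p = 0.0707 and 0.115) or replicate 3 (adjusted p = 0.0566 and 0.0673), nor did TGH without wild-type replicate 2 or 3 (adjusted p = 0.111 and 0.0772) or with a floor at log2 of 4 (adjusted p = 0.0525). AGO7 and DDL did not pass, and neither did the list of 4 (camera adjusted p = 0.720).

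Of the 23 measured genes on the added list for cell division and DNA replication, 14 fell and 9 did not pass. The histone chaperone gene ASF1B fell by 1.97 on the log2 scale and HTR12, the centromeric histone H3, from 10.10 ± 0.11 to 8.22 ± 0.08 (adjusted p = 4.92e-05). HTR12 is 1 of the 100 measured genes nearest DCL1, a region where 46% of genes were called. The list had a median of -0.96 (camera adjusted p = 8.72e-05, and adjusted p = 0.321 with an estimated correlation). Of the fixed cell cycle list 3 genes were measured, of which AUR1 and AUR2 are also on the added list. PRL, a subunit of the MCM replicative helicase, fell by 1.49 and the Aurora kinase gene AUR2 by 0.87, while AUR1 differed by -0.38 ± 0.14 (adjusted p = 0.0669). All 3 passed when adjusted over the list alone, and the list as a set did not (camera adjusted p = 0.0984). Leaving out the arrays numbered 1, 18 of the 23 on the added list fell.

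On the added list of meristem and lateral organ genes 11 of 24 fell, 2 rose and 11 did not pass. YAB3, a YABBY gene of the abaxial side of organs, fell from 10.82 ± 0.30 to 6.91 ± 0.44 (adjusted p = 1.71e-05) and JAG, which promotes organ growth, from 5.90 ± 0.13 to 2.35 ± 0.38 (adjusted p = 2.40e-05). NGA4 rose by 1.57 ± 0.25 (SE) and HWS by 0.78 ± 0.24. The list's median was -0.71 (camera adjusted p = 0.00653, and adjusted p = 0.225 with an estimated correlation). The call was lost with a floor at log2 of 4 (adjusted p = 0.155) and among probe sets brighter than the median (adjusted p = 0.812) or at log2 of 5 or more (adjusted p = 0.0503). When the arrays numbered 1 were left out, 3 rose and 13 fell. With the floor 6 fell, centring on the reference genes gave 1 rise and 16 falls, and 1 rose without replicate 2 or 3 of either genotype.

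The fixed lists of embryo poles held few measured genes, and YAB3, CLV3, YAB5 and BBM among them are also on the meristem and organ list above. YAB3 and CLV3, the signal peptide gene of the shoot meristem, fell in the shoot pole list, CLV3 by 1.44 from a low wild-type value of 3.07 ± 0.58, while YAB5 differed by 0.34 ± 0.32 (adjusted p = 0.441; camera adjusted p = 0.137). With a floor at log2 of 4 CLV3 did not pass, since all its values lie below it. BBM, an AP2-type factor of embryogenic growth, and the receptor kinase gene CR4 were the 2 measured genes of the root pole list and fell by 1.59 and 0.92. In both lists the same 2 genes passed over the list alone.

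Auxin response genes split. LBD16, a factor of lateral root formation, rose from 4.56 ± 0.15 to 9.61 ± 0.14 (adjusted p = 2.82e-06) and IAA29 by 0.81. IAA29 did not pass with a floor at log2 of 4, since all its values lie below it. WES1 and GH3.3, which encode enzymes that conjugate auxin to amino acids, and IAA30 fell, WES1 by 2.54 ± 0.44 (SE). The other 2 of the 7 measured did not pass, and over the list alone 3 rose and 4 fell. The mean difference was -0.028 and the median -0.53 (camera adjusted p = 0.915), while fry gave the direction as upward (adjusted p = 0.0324).

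**Figure D3:**
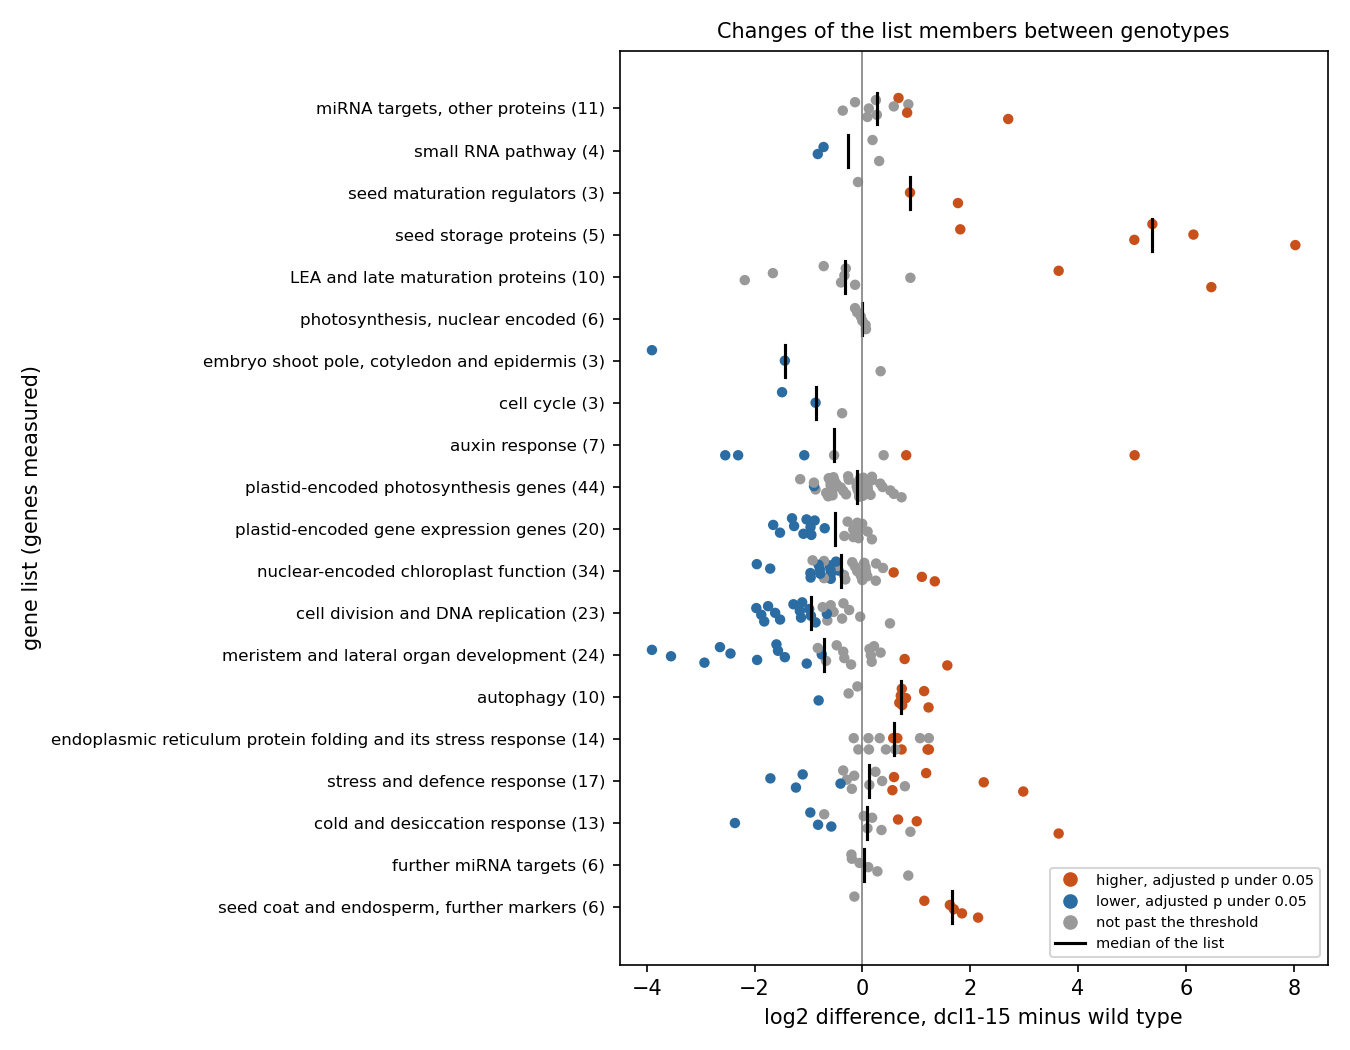
Difference between genotypes on the log2 scale (horizontal axis, dcl1-15 minus wild type) for each measured gene of the lists with at least 3 measured genes (vertical axis), coloured by the limma call, with the median of each list as a black line. The 5 storage genes lie between 1.81 and 8.03, and the cell division list has its median at -0.96.

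Of 20 plastid-encoded genes for transcription, translation and splicing, 10 fell, among them rpoC1, an RNA polymerase subunit, by 1.65 ± 0.32 (SE) and the ribosomal protein gene rps18 by 1.53 ± 0.26 (median of the list -0.52; camera adjusted p = 0.0115, and adjusted p = 0.264 with an estimated correlation). Of 44 plastid-encoded photosynthesis genes ndhH fell, by 0.90, and 43 did not pass (camera adjusted p = 0.598). With a floor at log2 of 4, without wild-type replicate 3 or without dcl1-15 replicate 2, 6 of the first list fell. Its call was lost with both filters on dim probe sets (adjusted p = 0.0893 and 0.0619). The gene ndhH, at a wild-type mean of 3.86, did not pass without wild-type replicate 3 or dcl1-15 replicate 1 or 2 (adjusted p = 0.0634, 0.0628 and 0.0753) or with a floor at log2 of 4 (adjusted p = 0.531). With the arrays numbered 1 left out, 13 of the first list fell, and 7 of the second rose and 8 fell. With the replicate number as a block, 2 of the second rose and 10 fell, and 4 fell with quantile normalization or centring on the reference genes. With 1 array left out 0 to 4 of the second rose and 0 to 8 fell.

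Of the 34 nuclear genes for chloroplast function, 13 fell, 3 rose and 18 did not pass. PAM68, a photosystem assembly factor, fell by 1.96 ± 0.24 (SE) and CHLI2, a magnesium chelatase subunit, by 1.71 ± 0.21, whereas LHCB4.3, NdhS and PRK rose, LHCB4.3 by 1.34 and PRK by 0.58. The list's call (median -0.39; camera adjusted p = 0.0425, and adjusted p = 0.238 with an estimated correlation) was lost without the arrays numbered 1 (adjusted p = 0.146), when 3 rose and 15 fell. With the floor or without dcl1-15 replicate 1 or 2, 8 fell. It was also lost without wild-type replicate 1 or 3 or dcl1-15 replicate 1 (adjusted p = 0.0769, 0.0829 and 0.0846), and with the dim filters, the floor, median centring or eBayes without the trend. In the fixed chlorophyll list PORB fell by 0.78 and CHLM differed by -0.34 (adjusted p = 0.0668), and both passed over the list alone. These 2 genes, and the 6 nuclear photosynthesis genes below, are also among the 34. PORB did not pass with the floor (adjusted p = 0.0780). CHLM fell with the replicate number as a block (adjusted p = 0.0357), and both genes fell when arrays were centred on the reference genes or those numbered 1, or wild-type replicate 1 alone, were left out. None of the 6 measured nuclear photosynthesis genes passed in limma, 0 had an unadjusted p under 0.05 and 0 passed with Welch's test (camera adjusted p = 0.915). LHCB4.1, a photosystem antenna gene, measured 12.88 ± 0.19 in wild type and 12.88 ± 0.03 in dcl1-15.

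Of 10 autophagy genes 7 rose and 1 fell. All but ATG3 belong to the ATG8 family, and ATG3 differed by -0.09 (limma adjusted p = 0.682), so the rises are those of 1 gene family. ATG8H and ATG8B, which encode ubiquitin-like proteins of the autophagosome, rose by 1.23 ± 0.20 (SE) and 1.14 ± 0.20, and ATG8E fell by 0.81 (median of the list 0.72; camera adjusted p = 0.0246, and adjusted p = 0.353 with an estimated correlation). ATG8H and ATG8E did not pass with a floor at log2 of 4 (adjusted p = 0.276 and 0.0617), and 4 of the 10 rose with it. Without dcl1-15 replicate 2, 4 rose, and 0 fell without any 1 dcl1-15 array or wild-type replicate 3. The autophagy call was lost with that floor (adjusted p = 0.0741) and with both filters on dim probe sets. Of 14 genes for protein folding in the endoplasmic reticulum and its stress response 5 rose, led by the transcription factor genes BZIP60 by 1.23 ± 0.25 and BZIP17 by 1.21 ± 0.25 (median 0.59; camera adjusted p = 0.0115, and adjusted p = 0.225 with an estimated correlation). With the arrays numbered 1 left out, 7 autophagy genes rose and 1 fell, and 7 folding genes rose. Of the folding genes 8 rose with the replicate number as a block, and 3 when arrays were centred on the reference genes or without replicate 2 or 3 of either genotype.

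Stress genes went both ways. Of 17 stress and defence genes 5 rose and 4 fell, with the thionin gene THI2.1 higher by 2.98 ± 0.36 (SE) and JMT, a jasmonate methyltransferase, by 2.25 ± 0.39 (camera adjusted p = 0.636). Centring on the reference genes left 3 rises, the floor 2 rises and 3 falls, and leaving out dcl1-15 replicate 2 gave 3 rises and 2 falls. Of 13 cold and desiccation genes 3 rose and 4 fell, with the dehydrin gene COR47 lower, at 8.10 ± 0.52 in wild type and 5.73 ± 0.34 in dcl1-15 (camera adjusted p = 0.702). AtLEA4-1 and OLEO3, among the rises, were already counted in the LEA and oil body lists. In the fixed heat shock and defence list, STZ rose by 0.59 from a low value of 2.46 ± 0.09 and PDF1.2 did not pass, with the same result over the list alone. Both genes are also among the 17 stress and defence genes. STZ did not pass when arrays were centred on the reference genes (adjusted p = 0.0626), without dcl1-15 replicate 2 (adjusted p = 0.0561) or with a floor at log2 of 4, since all its values lie below it.

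Leaving out the arrays numbered 2 or 3, in place of those numbered 1, lowered most of these counts, while the 5 storage and 2 oil body genes rose both times. Without the arrays numbered 2, 4 cell division genes, 9 meristem and organ genes, 3 plastid genes for gene expression and 6 nuclear chloroplast genes fell. In that fit 1 autophagy gene, 1 folding gene, 2 stress and defence genes, 1 of the 11 other miRNA targets and 4 of the 6 markers rose. Without the arrays numbered 3, 5, 11, 3 and 6 genes of the same lists fell, and 4, 2, 3, 1 and 2 rose. CR4, rps18 and BZIP17 passed in neither fit, ATG8B and BZIP60 did not pass without the arrays numbered 2, and the call of the 13 miRNA targets was lost without those numbered 3, at a mean difference of 0.54.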

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

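The tests with the replicate number as a term and with both arrays of a number left out were chosen after the counts of calls had been seen.

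Among the array control probe sets, which the comparisons above do not use, all 5 ubiquitin probe sets were higher on all 3 dcl1-15 arrays than on any wild-type array and 2 passed, by 0.42 for the 3' probe set and 0.52 for the middle one (limma, adjusted p = 0.0493 and 0.0339 over the 37 controls), while with Welch's test 0 of the 5 passed. Under quantile normalization and both centrings the differences of these 2 were 0.28 to 0.57, all upward. A further 8 control probe sets were higher on all 3 dcl1-15 arrays, namely 4 for GAPDH (0.18 to 0.34), 1 for actin (0.15) and 3 for cre, a transcript added to each sample at hybridization (0.17 to 0.22). None of these passed in limma (adjusted p = 0.0765 to 0.235) or with Welch's test, 6 had an unadjusted p under 0.05, and the lowest cre difference was -0.041 under quantile normalization.

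The count of changed probe sets was weighed first. Of the 10 splits of the 6 arrays into 3 and 3, 1 called as many as the real split, itself, with 6702, and the highest of the others called 0 (limma, 997 at an unadjusted p under 0.05 in the highest), and 10 splits are too few for a share under 0.05. A shift shared by the arrays of a number cancels in the genotype difference, because each number holds 1 array of each genotype, so by design it cannot be the source. With the number as a term 8425 probe sets were called, 6699 of the 6702 among them. The term leaves every difference unchanged, so this count adds no evidence on the source. Leaving out both arrays of number 1, 2 or 3 gave 8905, 2493 and 3151 calls, so the loss of 2 arrays alone does not set the count. Without the arrays numbered 1 the median SD was 0.13 in both genotypes, against 0.27 in wild type and 0.21 in dcl1-15 with all arrays. The counts of 2493 and 3151 met the fall predicted if 1 number made the calls. In each of these 3 fits all 6702 called probe sets kept their direction. These probe sets were called on the same arrays, which favours a kept direction. Whether 1 number makes the calls is therefore not decided. How much a number adds to the size of a difference was not tested. The genotype and any difference in the stage of the embryos collected stay open and were not tested apart.

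Genes near DCL1 were called more often than most. Of the 100 measured genes nearest DCL1, 46% were called, 23 higher and 23 lower, against a median of 39% and a 95th percentile of 45% over 91 other windows of 100 neighbouring genes, the highest of which reached 50%. This is consistent with variants of the Ws accession kept beside the mutation, the explanation the window was chosen to test. The window exceeds the median of the others by few genes, so such variants may account for calls there, HTR12 among them, and calls elsewhere were not tested for it. AT1G03890 lies in the next window, where 32% were called, and an effect of the genotype on these genes was not tested apart.

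The rise of all 5 storage genes, with 2 LEA genes, was weighed against a single deciding array and against RNA from seed coat or endosperm carried over with the mutant embryos. With any 1 array left out, the lowest count of these genes called higher was 7, of 7 with all arrays, which argues against the first. The markers' median of 1.66, with 5 of 6 higher, meets what carry-over predicts, and carry-over may contribute. In dcl1-15 DELTA-VPE measured 10.67 and AT1G71250 11.33, and with no detection calls it is not known how many of the markers embryos express. In 4 of the 5 storage genes the rise exceeded the markers' largest, 2.15. Most markers had higher wild-type levels than these 4 genes, so against those markers the sizes of the rises do not weigh against carry-over. BAN and AT5G26630, with low wild-type means of 2.58 and 2.60, differed by 1.85 and -0.15, less than these 4 genes. Both lie near the low end, so they do not decide it. Carry-over, the genotype and any difference in the stage of the embryos collected all stay open and were not tested apart.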

How the results depend on the processing

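Leaving out the arrays that share a number was chosen after the data were seen. The counts of changed probe sets (6702, with 3140 higher and 3562 lower) moved by over 1.5 times where fewer probe sets or larger changes were asked for: 3369, 1505 and 1864 among those brighter than the median; 3649, 1701 and 1948 with 1 probe set per gene; 3889, 1984 and 1905 at 2-fold; 2264, 1245 and 1019 with treat. A floor at log2 of 4 gave 4161, 1886 and 2275, with 34 of 110 called list members lost, and Welch's test 2082, 997 and 1085; the cause was not tested. With 1 array left out the lower calls numbered 2293 (without dcl1-15 replicate 2) to 4463; 2493, 1327 and 1166 were called without the arrays numbered 2 and 3151, 1702 and 1449 without those numbered 3. With the replicate number as a block 8425 were called, 3834 higher and 4591 lower, and no call of a list as a set or of a gene taken by the naming rule changed; of 257 list members, 26 gained a call, CHLM among them, and 0 lost it.

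Of the 9 fixed lists tested, 1 passed (storage), against 2 with the floor (cell cycle added), 0 with an estimated correlation (storage at the same mean of 5.28, adjusted p = 0.219, range 3.85e-08 to 0.219) and 7 with fry, which asks another question. fry turned auxin response upward at its mean of -0.028 (adjusted p = 0.0324, against 0.329 to 0.956 over the camera settings). The 13 miRNA targets lost their call among probe sets brighter than the median (mean 0.75, p = 0.100, range over the camera settings 0.0246 to 0.100) and with an estimated correlation (0.58) and without the arrays numbered 3 (0.54); with 1 array left out the mean was 0.55 to 0.60. The causes were not tested. Of 947 values of named genes over the settings, 893 kept direction and call, 53 lost the call, 1 gained it and 0 reversed; of 432 of the lists, 399 kept it, 26 lost it, 6 gained it and 1 reversed. Without the arrays numbered 1, 2 and 3, 0, 13 and 11 of the 50 named genes past the threshold lost the call. No alternative was run for the level of DCL1. With no detection calls, signal over background is unknown, which limits genes near the low end.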

Other observations

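Gene families grouped by the stem of their symbol were tested after the fixed lists, 40 families with at least 5 measured genes. None passed adjustment with camera, 11 had an unadjusted p under 0.05, 9 of them higher and 2 lower, and with an estimated correlation 3 had one. The families named here were chosen after their values were seen. Of 16 beta-glucosidase genes (BGLU) 10 rose and 1 fell, with BGLU29 higher by 4.85 ± 0.39 (SE) (limma adjusted p = 4.58e-05) and BGLU47, which fell by 1.08 (family adjusted p = 0.0535, and adjusted p = 0.512 with an estimated correlation). Of 5 xyloglucan endotransglucosylase/hydrolase genes (XTH), which remodel cell walls, 4 rose, XTH19 by 2.77 ± 0.23 and XTH16 by 2.14 ± 0.24 (family adjusted p = 0.0535). Of 8 aldehyde dehydrogenase genes (ALDH) 4 rose, led by ALDH7B4 at 0.88 ± 0.12 (family adjusted p = 0.0535). Of 7 OTP genes, pentatricopeptide repeat proteins that process organelle transcripts, 5 fell, OTP81 by 1.81 and OTP84 by 1.29 (family adjusted p = 0.109).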
